A study of Mus musculus with 6 samples.

How the data were processed

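The series measured guide abundance by amplicon sequencing of genomic DNA from mouse Hepa1-6 cells. Per the labels' protocols, genomic DNA was extracted with a column kit and guide sequences were amplified in 2 rounds of PCR, of 24 and then 8 cycles, the second adding index and adapter sequences. The deposited table holds, per the file headers, raw counts for each guide and sample, which are whole numbers and are not normalized. It also holds values headed normalized counts, which are treated here as a signal made by the authors: in each sample they equal the raw counts times 1 constant, namely 0.640, 0.509 and 0.464 for the in vitro samples and 32.7, 3.65 and 88.5 for the liver samples. The rule behind these constants, the counting tool, the read matching and the Cas9 system are not given in the sources used here. The signal columns were used only to find these constants. No genome build is stated, and no coordinates are printed. Gene names are those of the table: of 20263 names, 18965 are current symbols in the RefSeq gene table of assembly GRCm38.p6, 1186 are listed there as older names, and 112 matched neither. There are 25 names that read as dates, the form a spreadsheet gives to septin, March and deleted-in-esophageal-cancer genes, and these stayed unnamed.

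Samples were grouped by their labels into in vitro and liver metastatic tissue, with 3 in each. Total counts ran from 16253450 to 40224793. No 2 libraries agreed within sampling noise, so each counted as 1 replicate. The groups compared, the tests, the gene lists, the named-gene rule and most alternatives were fixed before the data were examined. Those added later are named as such in the closing section.

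Guide counts were tested with edgeR 4.0.16 in R 4.3.3: guides were kept by filterByExpr with a minimum count of 10, scaled by TMM, and fitted by the robust quasi-likelihood method with group as the only term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. This kept 11522 guides. Guide fold changes are liver metastatic tissue over in vitro. Genes with at least 3 tested guides (158) were ranked by robust rank aggregation, written in Python 3.11.15 with numpy 2.4.6: one-sided guide p-values were ranked, and ranks up to a fraction of 0.25 counted. Gene p-values came from 1000000 sets of uniform random ranks of the same size. For genes they are called permutation p below, although no guides of these data were permuted. Gene lists were tested with limma 3.58.1 (camera, preset correlation 0.01) over lists with at least 5 tested guides, 22 of 23. The value given for a list is the median guide log2 fold change minus that of all tested guides. The 21 lists fixed from gene names cover essential complexes, tumour suppressors, immune recognition, phagocytosis, glycosylation, adhesion, growth signalling, metabolism, hepatocytes, macrophages and lymphocytes. Olfactory receptor and non-targeting guides were added as references. CPM is the count divided by the library total and multiplied by 1000000. Measures of library complexity were compared by exact permutation tests over the 20 assignments of 3 and 3 libraries, which cannot go below p = 0.1. Shares of guides were compared by Fisher's exact test with scipy 1.17.1, with Wilson 95% intervals.

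Genes named in the text are Ermap, Lgals9 and Clec4n from the series title, the 10 genes with the smallest enrichment p and the 10 with the smallest depletion p, up to 4 members of a list that passes and up to 2 of other lists by rank aggregation p, the 5 guides with the highest mean CPM in liver tissue and up to 5 guides that pass. Microrna and control entries are left out of the counts of 10. Other names were chosen after their values were seen and are said to be.

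The alternatives tried were DESeq2 1.42.0 size factors, total counts and non-targeting guides as scaling, no filter and a stricter filter (a mean of 100 counts in either group), DESeq2's Wald test, the replicate number as a block, each library left out, counts summed per gene, other settings of the rank aggregation, and subtraction of reads that may be carried between libraries. Guides were called abundant in a liver library, whatever their in vitro level, when they had at least 1000 counts and over 5 times the 0.1% of their counts in the other 5 libraries.

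The pipeline was tested on simulated counts for the 3 in vitro and 3 liver libraries, with 200 genes changed. Of guides raised 16-fold 38.1% were recovered, of those raised 256-fold 80.4%, and of those lowered 16-fold and 256-fold 15.5% and 33.0%, among 11454 guides. Genes with at least 2 tested guides were recovered in 100% of cases when raised, and in 18.0% and 42.6% when lowered 16-fold and 256-fold. Of 181 guide calls 9 were unchanged guides. These rates hold for the simulated counts only. It was not tested whether those counts reproduce liver libraries in which the 10 most abundant guides took a mean of 96.0% of counts. The rates therefore give no recovery or error rate for the real comparison. Splits of the real libraries that mix in vitro and liver called 11 to 39 guides. Random guide p-values gave a gene p under 0.05 in 4.71% of 1976 genes.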

Results

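Guide abundance was measured in 6 libraries of a pooled CRISPR knockout screen in Hepa1-6 cells, a mouse hepatocellular carcinoma line. In such a screen each cell carries a guide RNA that directs Cas9 to a gene, and the guide read from genomic DNA serves as the barcode of that cell and its descendants. There were 3 libraries from cells grown in vitro and 3 from liver metastatic tissue. The table lists 61139 guides, of which 60139 target 20263 gene names and 1000 are non-targeting controls. Total counts were 22068177, 26361748 and 28405189 in the in vitro libraries and 16253450, 31948463 and 40224793 in the liver libraries (exact two-sided permutation p = 0.7). By its design statement the series looked for genes that affect liver metastasis of these cells, and its title names ERMAP, galectin-9 and dectin-2. The labels do not say whether the 3 libraries of a group came from separate cultures or animals. The spread between these libraries may therefore be technical. Exact permutation p-values measure only that spread, and edgeR p-values measure it with variance shared across guides. The p-values of rank aggregation and Fisher's exact test compare guides with each other and do not measure it. Amplicon reads without molecular identifiers are not independent molecules, and the intervals and detection floors below cover counting error only.

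In the cultured cells fewer guides were found against genes that dividing cells need than against olfactory receptors. The starting library is not analysed here, so these shares compare lists with each other and not with the guides before infection. A guide was called present when it had at least 10 counts in at least 2 of the 3 in vitro libraries. Of the olfactory receptor guides, whose targets liver cells do not need, 30.7% were present (1013 of 3305, Wilson 95% interval 29.1 to 32.2), and of the non-targeting guides 30.8% (308 of 1000, interval 28.0 to 33.7). Only 5.80% of guides against cytosolic ribosomal proteins were present (13 of 224, Fisher's exact adjusted p = 7.62e-18 over 22 lists), and 6.14% of those against DNA replication genes such as the MCM helicase subunits (7 of 114, adjusted p = 4.77e-09). The share was 10.8% for the proteasome (10 of 93, adjusted p = 7.27e-05) and 15.2% for the spliceosome and RNA polymerase II (20 of 132, adjusted p = 0.000503). Together these 4 lists had 50 of 563 guides present, or 8.88%, against 30.7% of olfactory receptor guides (odds ratio 0.221, Fisher's exact p = 1.68e-31), and the share per in vitro library was 9.65% ± 0.57 (SD, n = 3) against 30.8% ± 1.31 for olfactory receptors.

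Guides against oxidative phosphorylation genes, the mitochondrial respiratory chain and ATP synthase, were present at 17.5% (30 of 171, adjusted p = 0.00093). Those against mTORC1 and PI3K activators, which drive growth signalling, were present at 19.8% (25 of 126, adjusted p = 0.0363). With a minimum of 1 count in place of 10 the mTORC1 and PI3K list did not pass (adjusted p = 0.183). In the other 16 lists the share ran from 18.8% for galectins (6 of 32) to 34.7% for tumour suppressors (51 of 147), with adjusted p from 0.0907 to 1. The planned measure, the difference in median log2 CPM between essential and olfactory receptor guides, was 0 in each in vitro and each liver library because most guides of each kind had no counts. The shares above were therefore chosen after the data were seen. Among guides with at least 1 count, the essential lists lay 0.42 ± 0.13 log2 units (SD, n = 3) below olfactory receptors in the in vitro libraries, as a mean difference of -0.42. The Fisher tests treat guides of 1 gene as independent.

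**Figure D1:**
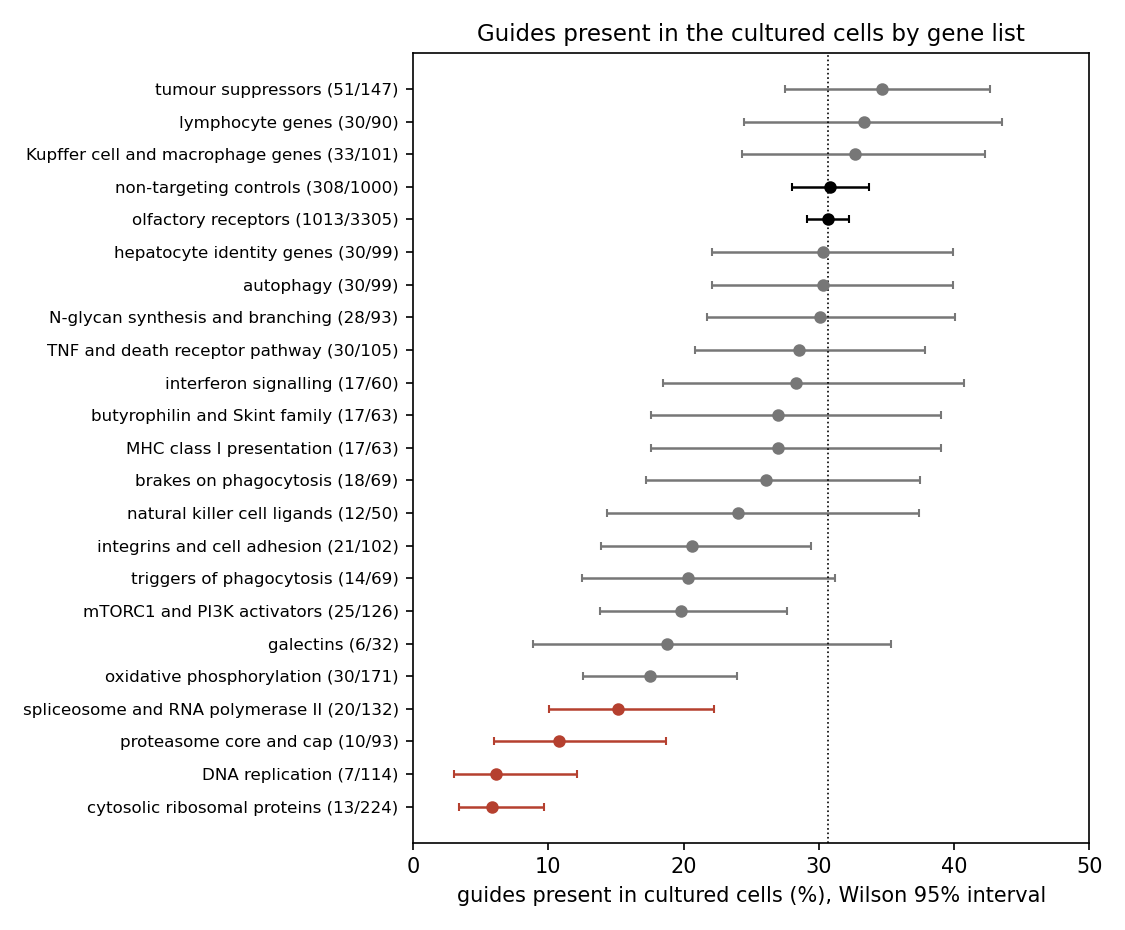
Share of guides present in the cultured cells for each of 23 gene lists, in percent (horizontal axis), with Wilson 95% intervals. Red marks the 4 essential lists, black the olfactory receptor and non-targeting references, and the dotted line the olfactory receptor share of 30.7%. The 4 red lists lie between 5.80% and 15.2%.

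In liver metastatic tissue a few guides made up nearly all counts. A guide against Mybpc3, which encodes cardiac myosin-binding protein C (MGLibB_32765, ACGGTCACCTCACCATCCTG), had 9201819, 8251103 and 8628611 counts in liver libraries 1 to 3, or 56.6%, 25.8% and 21.5% of each library. Its level was 346306 ± 191639 CPM in liver tissue and 1688 ± 800 CPM in vitro (SD, n = 3 each), 205 times higher, and each liver library lay above all in vitro libraries (exact permutation p = 0.1). Liver library 1 was further led by guides against Il4ra (21.8%), the interleukin-4 receptor subunit, and Fstl5 (13.1%). Liver library 2 was led by an Olfr1084 guide (34.9%), with Npc1l1, an intestinal cholesterol transporter, at 12.6% and Prph2 at 3.79%. In liver library 3 guides against Olfr1431, Zscan18, Rnf208 and Akap11 held 21.3%, 17.4%, 16.1% and 13.9%. Of these, Olfr1084 had 0.129% of liver library 1 and 0.0260% of liver library 3, and Il4ra had 0.135% and 0.133% of liver libraries 2 and 3. The Il4ra, Olfr1084, Olfr1431 and Zscan18 guides averaged 73633 ± 125217, 116836 ± 201028, 71663 ± 122106 and 58167 ± 100142 CPM in liver tissue (SD, n = 3), with the spread above the mean in each because 1 library held most of the counts. The guides against Fstl5, Npc1l1, Prph2, Rnf208 and Akap11 were named after their values were seen.

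The 10 most abundant guides took 96.0% ± 4.57 of counts in liver tissue and 1.32% ± 0.454 in vitro (SD, n = 3 each). The effective number of guides, the exponential of the Shannon entropy, was 6.52 ± 2.51 in liver tissue and 10877 ± 842 in vitro. Guides with at least 1 count numbered 12211 ± 2510 in liver tissue and 21380 ± 140 in vitro, and those with at least 10 counts 628 ± 382 and 18022 ± 626. The Gini index, which is 1 when a single guide holds all counts, was 0.99976 in liver tissue and 0.859 ± 0.00955 in vitro. Each of these differences had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows, and an adjusted p of 0.114 over 8 measures. No count in any library was listed for 34389 guides, or 56.2%, and 15856 had counts in all in vitro libraries. Whether low counts were removed before the table was made is not given in the sources used here, so a 0 may not mean absence from the cells.

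**Figure D2:**
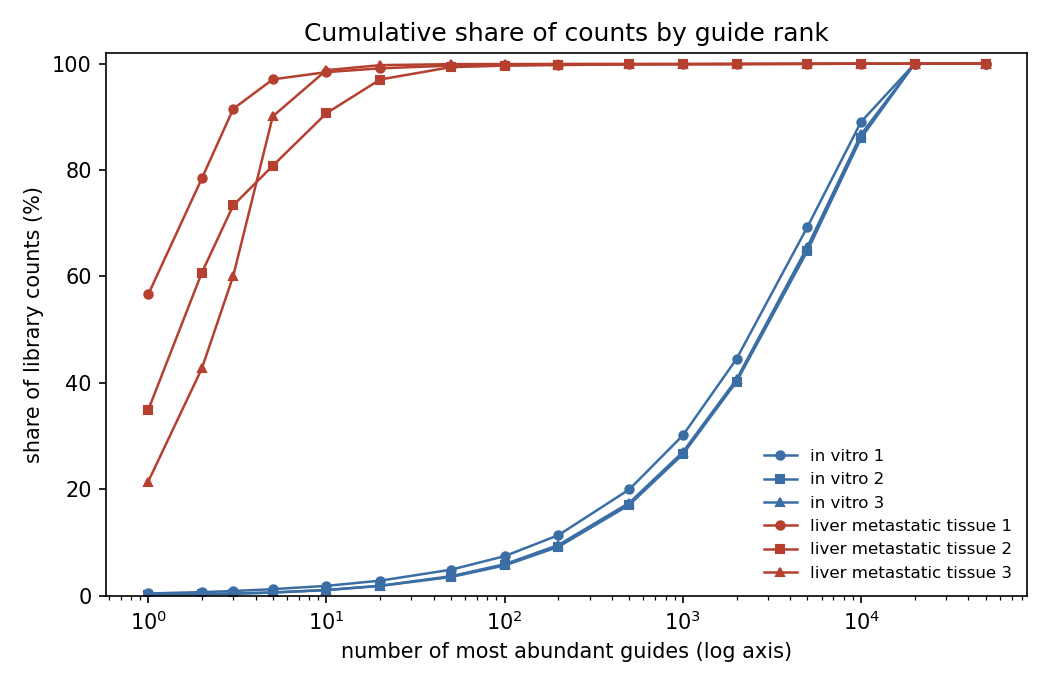
Cumulative share of each library's counts (vertical axis, percent) held by its most abundant guides (horizontal axis, number of guides, log axis). Blue lines are the 3 in vitro and red lines the 3 liver metastatic tissue libraries. The 10 most abundant guides held 90.7% to 98.8% of each liver library and 1.05% to 1.85% of each in vitro library.

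Among the genes named in the series title, Ermap rose in liver metastatic tissue. Ermap encodes erythroid membrane-associated protein, a cell surface protein of the butyrophilin family. The guide MGLibB_16526 (TTCTGTGGTCTTGCCCGTCT) went from 216 ± 78.8 CPM in vitro to 997 ± 639 CPM in liver tissue (SD, n = 3 each), 4.61 times, with 2911, 6020 and 8180 counts in vitro and 14702, 53581 and 16447 in liver tissue. MGLibB_16524 (ACCACAGAAAGAGCCACCGC) had 18.7 ± 20.1 CPM in vitro and 309 ± 309 CPM in liver tissue, 16.5 times, with 328, 1066 and 21 counts in vitro and 4461, 20251 and 747 in liver tissue. MGLibB_16525 (TCCCAAAGCCGTGGACTGAG) had 0.579 ± 0.305 and 285 ± 247 CPM, 492 times. With a library left out the ratio of MGLibB_16526 ran from 3.04 (without liver library 2) to 5.97, that of MGLibB_16524 from 7.84 (without liver library 2) to 39.6 (without in vitro library 2), and that of MGLibB_16525 from 358 to 738. The first guide was above all in vitro libraries in 3 of 3 liver libraries (exact permutation p = 0.1), and the other 2 guides each in 2 of 3 (exact permutation p = 0.2 each). Guide MGLibB_16525 had 6730 and 17714 counts in liver libraries 1 and 3 but 18 in liver library 2, and 20, 8 and 15 in the in vitro libraries, where 0.1% of its counts in the other libraries would come to about 24.5.

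**Figure D3:**
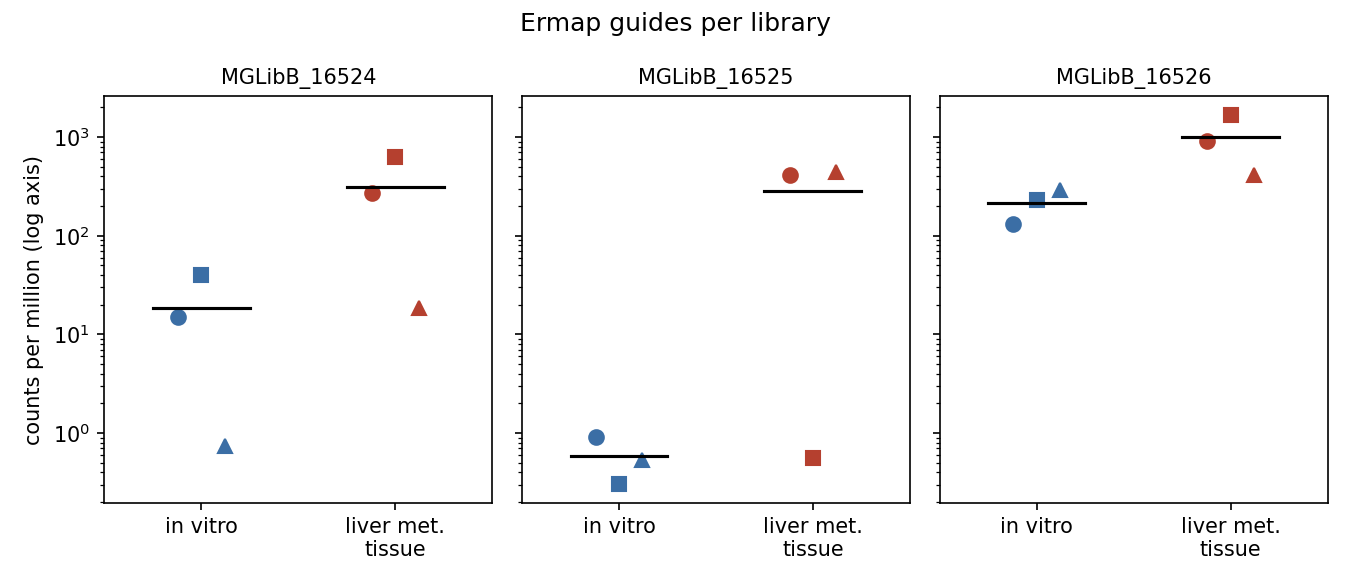
CPM (vertical, log axis) of the 3 Ermap guides in each in vitro (blue) and liver metastatic tissue (red) library, 1 panel per guide. Circles, squares and triangles are replicates 1 to 3 and black lines are group means. Liver means were 309, 285 and 997 CPM for MGLibB_16524, MGLibB_16525 and MGLibB_16526, each above the in vitro mean, while liver library 2 held MGLibB_16525 at 0.563 CPM.

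By robust rank aggregation of the guides, Ermap had a permutation p for enrichment of 1e-06, the smallest that 1000000 sets of random ranks can give, and an adjusted p of 0.000158 over 158 genes. That p measures how far its 3 guides rank together and not the spread between libraries. By that spread the exact permutation p of the guides was 0.1 for MGLibB_16526 and 0.2 for each of MGLibB_16524 and MGLibB_16525. The title names Ermap as an outcome of the study, so the value over its 3 genes alone (3e-06) is no independent test, and the other 2 genes had no p. The edgeR quasi-likelihood log2 fold changes of its guides were 11.60 ± 3.94, 13.27 ± 4.26 and 18.76 ± 4.90 (SE), with adjusted p of 0.489, 0.466 and 0.259 over 11522 guides, so no single Ermap guide passed. With total counts as the scaling these were 1.95, 3.79 and 8.70 log2 units, with edgeR adjusted p of 0.00306, 0.0842 and 0.0294. The first and the third guide thus passed under that scaling, where 28 of 11522 guides passed as enriched and 11255 as depleted. With nearly all guides past the threshold, adjustment hardly changed their edgeR p (0.00298 and 0.0287 unadjusted). The gene kept its rank aggregation p of 1e-06. Lgals9, which encodes galectin-9, a glycan-binding lectin, could not be tested: its 3 guides had no count in any library, which allows up to 0.136 CPM in the smallest in vitro library (3 counts). Clec4n, which encodes dectin-2, a C-type lectin receptor of macrophages, had counts for 1 of its 3 guides: 11831, 11748 and 17280 in vitro and 8, 29 and 119 in liver tissue. Its log2 fold change was 1.58 ± 2.14 (SE, edgeR adjusted p = 1), and -8.74 with total counts as the scaling, which moves nearly all guides down. Relative to the median of all guides it lay at 1.96 and 1.24 under these 2 scalings.

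Across genes, Ermap was the only one of the 158 with 3 tested guides whose guides rose together past the threshold, and 0 genes were depleted. Ermap passed in 17 of 19 alternatives. It missed with no filter on low counts and with counts summed per gene (edgeR adjusted p = 0.595). After subtraction of carried reads it kept fewer than 3 tested guides. At an unadjusted p under 0.05, 7 genes were enriched and 7 depleted by rank aggregation, and with DESeq2 p-values in place of edgeR's the counts past the threshold were 1 and 0. The next genes by permutation p for enrichment were Prph2, a photoreceptor disc protein (p = 0.0121), Cdkn1a, which encodes the cell cycle inhibitor p21 (p = 0.0244), Lcn10 (p = 0.0277), Padi3 (p = 0.0355), Cacna2d3 (p = 0.0481), Gm382 (p = 0.0494), Dnajb4 (p = 0.0520), Aldh1a2 (p = 0.0552) and Olfr49 (p = 0.0675). All of these had an adjusted p of 0.698. The enrichment p comes from guide ranks and need not mean that all guides of a gene rose. The median guide log2 fold change was below 0 for Lcn10 (-0.35), Padi3 (-0.19), Cacna2d3 (-0.42), Aldh1a2 (-1.26) and Olfr49 (-0.52). For Cacna2d3, Aldh1a2 and Olfr49 it was also below the median of all tested guides (-0.39). Cacna2d3, Aldh1a2 and Olfr49 each had 1 guide with a high fitted value and 2 guides below that median. All guides of Lcn10, Padi3 and Gm382 had lower CPM in each liver library than in all in vitro libraries. In Prph2 and Cdkn1a 1 guide was abundant in liver tissue: MGLibB_43025 of Prph2 averaged 14668 ± 20305 CPM in liver tissue (n = 3) while its other 2 guides averaged 4.01 and 0.0705 CPM. MGLibB_09596 of Cdkn1a averaged 1286 ± 1750 CPM while the other 2 averaged 0.388 and 0.699 CPM. A further guide of each gene ranked high by fitted log2 fold change (MGLibB_43023 of Prph2 4.23, MGLibB_09595 of Cdkn1a 3.24, percentiles 96.5 and 95.5), but went from 100.5 to 4.01 CPM and from 47.3 to 0.699 CPM, lower in 3 of 3 liver libraries. The lowest permutation p-values for depletion were those of Cdcp2 (0.0197), Ctse, an aspartic protease (0.0232), Gm16442 (0.0400), Flywch2 (0.0413), Gm12886 (0.0445), Abcc8, a subunit of the pancreatic potassium channel (0.0455), Aldh1l1 (0.0485), Nmu, a neuropeptide (0.0671), Padi3 (0.0821) and Mkrn1 (0.0961), each with an adjusted p of 1. Guides of these genes had at most 8 counts in each liver library, apart from a Padi3 guide with 69 in liver library 1. Counts this small may be carried reads, so depletion could hardly be seen under this scaling. Fitted values of -11.55 to -12.28 came from guides with no count in any liver library.

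At the level of single guides, 1 of 11522 passed as enriched and 0 as depleted (edgeR), with 393 and 412 at an unadjusted p under 0.05 and 365 and 0 by DESeq2. The passing guide targets Sdha, a subunit of succinate dehydrogenase (MGLibB_47453), with 4, 1 and 11 counts in vitro and 7, 14 and 9 in liver tissue. Its log2 fold change of 10.23 ± 0.76 (SE, adjusted p = 1.50e-24) came with 0.202 ± 0.176 CPM in vitro and 0.364 ± 0.122 CPM in liver tissue (n = 3 each, exact permutation p = 0.2). The 5 guides with the highest mean CPM in liver tissue had log2 fold changes of 17.10 (Mybpc3), 17.21 (Olfr1084), 14.08 (Il4ra), 18.56 (Olfr1431) and 17.52 (Zscan18), with edgeR adjusted p of 0.259 for all but Il4ra (0.355). With a library left out the Mybpc3 value stayed between 16.82 and 17.56. It came to 9.82 for Olfr1084 without liver library 2, 9.22 for Il4ra without liver library 1, and 11.10 for Olfr1431 and 8.64 for Zscan18 without liver library 3. These fitted values depend on the scaling and are not rises in CPM. In CPM the Il4ra guide was above all in vitro libraries in liver library 1 and within their range in liver libraries 2 and 3. The Olfr1084 guide was below all in vitro libraries in liver library 3, and the Zscan18 guide in liver library 2. The Olfr1431 guide was above them in 3 of 3. The scaling decides how the rest reads. Among the 5534 guides with counts in all libraries, the median count was 2, 4 and 2 in the liver libraries against 1748, 2095 and 2232 in vitro. Liver counts of up to 10 rose with in vitro abundance (Spearman rho 0.595 to 0.697 across guides), and the median log2 fold change of all tested guides was -0.39. With total counts as the scaling that median was -9.97, and 28 guides passed as enriched and 11255 as depleted. Leaving out a library gave 0 to 16 enriched guides, namely 8, 8 and 16 without in vitro libraries 1, 2 and 3, 2 without liver library 1 and 0 without liver library 2 or 3.

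Of 22 gene lists, the triggers of phagocytosis, surface or secreted molecules that promote engulfment of a cell, were the only list past the threshold (camera adjusted p = 0.000201). The call was lost with adjusted p = 0.219 with an estimated correlation, where no list passed, and in the comparison of gene medians with random lists of matched abundance, where this list lay at percentile 60.7. Ermap and Lgals9 are members of this list and are named in the series title, so its call is no independent test. The 9 tested guides of the list had a median log2 fold change 0.91 above that of all guides. Of these, 6 lay above the overall median and 3 below, and the 3 that passed when adjusted over the list alone were the Ermap guides. The other 6 guides target Pros1, Anxa1, Lgals3, Slamf7, Vcam1 and Xkr8, and without Ermap the list did not pass (median 0.04 above all guides, camera adjusted p = 0.845). Over the 17 alternatives that give it an adjusted p it passed in 14, with adjusted p from 3.96e-19 to 0.845. Ermap is also in the butyrophilin and Skint list, whose 15 guides lay 0.19 above all guides (adjusted p = 0.277). That list passed with total counts as the scaling (adjusted p = 6.89e-07) and in 3 of 16 alternatives (adjusted p from 6.89e-07 to 0.645). Adjusted over the list alone, the 3 Ermap guides were higher and a Skint11 guide, with no count in any liver library, was lower.

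Lists of growth control did not pass by camera. The 38 tumour suppressor guides lay 0.00 from the overall median (adjusted p = 0.782), and 4 of them, against Rb1, Lats1, Rasa2 and Cdkn1a, had a positive log2 fold change that passed when adjusted over the list alone. Positive is relative to the scaling: in CPM the Lats1 guide was above all in vitro libraries in liver library 2 alone and below them in the other 2, the Cdkn1a guide (MGLibB_09596) was above in 2 and below in 1, and the Rb1 guide (MGLibB_44679) averaged 57.9 CPM in vitro and 0.350 CPM in liver tissue and the Rasa2 guide 9.17 and 2.48 CPM. By rank aggregation Cdkn1a had the smallest permutation p for enrichment among the tumour suppressors (0.0244), followed by Cic, a transcriptional repressor (0.566). The mTORC1 and PI3K activators lay 0.21 above (15 guides, adjusted p = 0.984), the spliceosome and RNA polymerase II 0.18 above (15 guides, 0.342), and ribosomal proteins 0.61 above (7 guides, 0.596). The proteasome lay at -1.81 (7 guides, 0.618, gene median at percentile 1.96 of random lists) and at 0.32 with its 3 guides at 0 in liver tissue set to their bound of 3 counts. Further lists were oxidative phosphorylation at -0.39 (19 guides, 0.782, or 0.39 with such guides at their bound) and autophagy at -0.21 (20 guides, 0.416). The spliceosome list passed with total counts as the scaling (adjusted p = 0.00255) and in 3 of 16 alternatives (adjusted p from 0.00255 to 0.987). Adjusted over the list alone, 1 spliceosome guide (Snrpd3) and 2 of oxidative phosphorylation (Sdha and Ndufa2) passed with a positive value. DNA replication had 2 tested guides and was not tested, but without liver library 1 it was tested and passed as enriched (camera adjusted p = 0.0213).

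Lists of immune recognition did not pass by camera either. Interferon signalling had the lowest p among them, at -0.57 against all guides (13 guides, 9 of them below the overall median, adjusted p = 0.189). MHC class I presentation lay at 0.13 (9 guides, 0.984), the TNF and death receptor pathway at -0.14 (20 guides, 0.797), natural killer cell ligands at 0.15 (9 guides, 0.984), brakes on phagocytosis at -0.07 (9 guides, 0.802), galectins at 0.32 (5 guides, 0.984) and N-glycan synthesis and branching at -0.19 (14 guides, 0.984). When adjusted over the list alone, 1 guide of the MHC list (Tapbpl), 1 of the brakes (Cd200) and 1 non-targeting control passed with a positive value, although in CPM the Tapbpl and Cd200 guides averaged 12.5 and 9.90 in vitro and 2.61 and 2.09 in liver tissue. Integrins and cell adhesion lay at -0.36 (12 guides, 0.782) and hepatocyte identity genes at 0.08 (22 guides, 0.984). Genes of other cell types served as markers that a hepatoma cell should not need: Kupffer cell and macrophage genes lay at 0.51 (20 guides, 0.782, gene median at percentile 99.3 of random lists), with Clec4e at a permutation p for enrichment of 0.117, and lymphocyte genes at 0.18 (19 guides, 0.913). Olfactory receptors lay at -0.03 (641 guides, 0.984), with Olfr49 and Olfr570 at permutation p of 0.0675 and 0.154, and non-targeting controls at 0.10 (210 guides, 0.913). Over all 22 tested lists, the median, mean and test did not share 1 sign in 11, among them Kupffer cell and macrophage genes (mean -0.52). With guides at 0 in liver tissue set to their bound the N-glycan median became 0.26.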

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

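The subtraction of carried reads (0.1% of a guide's counts in the other libraries), the list without Ermap and the shares of guides present were chosen after seeing the data. No called result reversed. Enriched guides numbered 1, against 2 with DESeq2 size factors, 28 with total counts, 3 with non-targeting guides as scaling, 138 with no filter, 26 with the stricter filter, 365 with DESeq2 (adjusted p not given for 10860 guides), and 25 and 9 after subtraction with TMM and with total counts. Leaving out a library gave 0 to 16: 8, 8 and 16 without in vitro libraries 1, 2 and 3, 2 without liver library 1, and 0 without liver library 2 or 3. Depleted guides numbered 0, against 11255 with total counts and 10621 and 10974 after subtraction with TMM and with total counts. Enriched genes numbered 1, against 0 with no filter and 0 after subtraction with either scaling, where Ermap keeps fewer than 3 tested guides, and 1 to 2 with a library left out (Atp9b joined without in vitro library 3, adjusted p = 0.0324). Ermap passed in 17 of 19 alternatives, with adjusted p from 0.000152 to 0.595. It missed with no filter, where more genes were tested (permutation p = 2.9e-05, adjusted p = 0.0521 over 1796 genes), and with counts summed per gene (0.00175 by edgeR, adjusted p = 0.595 over 9808 genes), and passed after subtraction with at least 2 guides (adjusted p = 0.0178). Passing lists numbered 1, against 3 with total counts, 2 with DESeq2, 2 after subtraction with either scaling, 0 with no filter, 0 with an estimated correlation, and 1 to 2 with a library left out (2 without liver library 1, with DNA replication, or 2, with butyrophilins). Gene medians against random lists gave 2 others in the outer 5% of random lists, unadjusted: Kupffer cell and macrophage genes (99.3) and the proteasome (1.96, from fitted values of guides at 0 in liver tissue whose bound turns the sign), while triggers of phagocytosis (60.7) dropped out. Where no construction shows it, the cause was not tested. The difference in detected guides, liver minus in vitro, was -9169, against -17393 at a minimum of 10 counts and -10556 to -8112 with a library left out. With the replicate number as a block 9 guides were enriched. Same-numbered libraries deviated with correlations of 0.0187, 0.00279 and -0.00214, so no pairing by number was detected. The check cannot exclude one, because detected guides had a median count of only 2, 2 and 1 in liver libraries 1 to 3. Of 816 values for named genes, guides and lists under alternatives, 793 stayed on the same side, 15 became and 8 ceased to be past the threshold. Of 121 values for the main results under alternatives, 87 were classed as the same, 32 as moved and 2 as weaker.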

Other observations

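All tests here were chosen after the result was seen, except the random assignment of genes to abundant guides and the test of tumour suppressors, whose outcomes were stated first. Guides that reached at least 1000 counts and over 5 times the carried level numbered 39, 74 and 33 in liver libraries 1 to 3 and held 99.1%, 99.5% and 99.8% of counts. Of 95 such guides, called abundant here, 60 were so in 1 liver library, 19 in 2 and 16 in 3. Abundance is not a rise: 74 of the 95 had CPM above all in vitro libraries in at least 1 liver library where they were abundant, and 21 in none, B4galt5 and Rb1 among them. The 6 above in 3 liver libraries target Mybpc3, Olfr1378, Ermap, Akap11, Dab2ip, a negative regulator of Ras signalling, and Snrpd3, a core spliceosome protein. These names were chosen after their values were seen. Non-targeting controls contributed 2 of 95, or 0.649% of the 308 present, and olfactory receptors 9, or 0.888% of 1013. Among tumour suppressors 3 of 51 present guides were abundant (Cdkn1a, Lats1 and Rb1), an odds ratio of 6.97 against olfactory receptors with a Fisher's exact adjusted p of 0.123. With only guides above all in vitro libraries these were 2 of 51 (Fisher's exact p = 0.0793, unadjusted), so the hypothesis that loss of tumour suppressors led to growth was neither borne out nor excluded. Triggers of phagocytosis (3 of 14) and the butyrophilin and Skint family (3 of 17) passed through the Ermap guides alone (Fisher's exact adjusted p = 0.00826 each). Both lists hold Ermap, which the series title names, so neither is an independent test. Single guides against the spliceosome (Snrpd3), interferon signalling (Tyk2) and oxidative phosphorylation (Ndufa2) were abundant too, with adjusted p of 0.785, 0.785 and 0.932.

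Guides with at least 100000 counts in 1 liver library occurred in all other libraries, at no less than 0.0234% of that count over 165 pairs of such a count with another library. For the 23 guides that high in exactly 1 liver library, counts in the other 2 rose with the high count (Spearman rho 0.463, permutation p = 0.0280). The partial rho given the in vitro counts was 0.171. These correlations do not tell reads carried between libraries, by index misassignment or handling, from abundance in culture. In the other liver libraries, guides of matched in vitro abundance lay below 0.02% of the high count in 100% of pairs. For the 27 high guides themselves this was 0% of 66 pairs, which argues against abundance in culture alone as the source of those liver counts. In the in vitro libraries the matched share was 0%, so there the 2 cannot be told apart. Of all pairs 57.6% lay above 0.5%, 55 with an in vitro and 40 with a liver library as the receiver. This share cannot decide whether carried reads were the whole cause. In the in vitro pairs carried reads cannot be told from abundance in culture. The liver pairs include guides high in more than 1 liver library, such as Mybpc3. The small liver counts of other guides may be carried reads, since counts of up to 10 rose with in vitro abundance across guides (lowest Spearman rho 0.595 of the 3 liver libraries, guides not being independent replicates), at 0.0328%, 0.0560% and 0.0261% of in vitro counts. The TMM scaling behind the fitted log2 fold changes may thus rest on carried reads, and rare surviving cells with those guides would look alike and stay open.

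The 27 guides with at least 100000 counts in a liver library have different target genes, 4 of them olfactory receptor genes where 1.54 would be expected from their share. If loss of the target drove the growth, the other guides of these genes should rank high: the 14 tested had a median log2 fold change percentile of 64.0 (one-sided permutation p = 0.127). Of the 54 other guides in the library 0 were abundant. That 0 was likely in any case, since 56.2% of all guides had no count in any library and only 95 were abundant. These values leave open whether loss of some targets contributed. Clone size in culture is a candidate explanation, since the median in vitro abundance percentile of the 27 guides was 94.6 after subtraction of carried reads (lowest 0.0075). The subtracted rate of 0.1% is assumed, while the in vitro counts of these guides had a median of 0.578% of the high liver count. The percentile may therefore itself include carried reads. Mutations acquired by single clones and chance seeding were not tested.

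Ermap was the only gene with at least 2 abundant guides, which alone is not rare (permutation p = 0.135), but all 3 were abundant and above all in vitro libraries in at least 2 liver libraries. Chance growth of unrelated clones is argued against, since 0.002% of 100000 random assignments gave any gene 3 abundant guides, and carried reads as the source of the highest counts are argued against because each guide had a liver library with more counts than its other 5 libraries together (at least 111% of them). A single common source of Ermap guides, such as 1 stray DNA pool, is argued against by guide ratios that differed up to 26679-fold between liver libraries, a value that rests on 18 counts in liver library 2, and up to 15.7-fold without that library. Guide MGLibB_16525 was the only abundant guide with fewer than 100 in vitro counts in total (43, against a median of 7174). Separate stray sources of single Ermap guides and growth of cells that lost Ermap both stay open, and no test here tells them apart.

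The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. All 10 gave at least as many guides as the real split (1, highest other 39). The splits that mix the groups called 11 to 39, and the reason was not tested. For genes 2 of 10 gave as many (1, highest other 1), and for gene lists 1 of 10 (1, highest other 0).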
